A study of Homo sapiens with 12 samples.

How the data were processed

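RNA of 12 MCF10AT libraries was measured: cells with the long and the intermediate prolactin receptor, the latter with intact or deleted I-tail, untreated or given PRL, 3 libraries per group per the labels. Libraries were polyA-selected from total RNA. The deposited table gives whole-number counts per Ensembl gene and library, and per the submitters' processing notes STAR 2.7.9a, featureCounts of Subread, FastQC and build GRCh38 were named. The annotation release, the strand setting and filters of the counting are not given in the sources used here. Groups were taken from the genotype and treatment labels, and the replicate numbers follow the order of the titles within a group.

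The table held 62703 entries. The 1 entry without values was left out, and 62624 of 62702 matched a gene symbol. Depth was 37086652 to 57324865 counts in intact untreated, 42023363 to 45121177 in intact PRL, 38209715 to 46684862 in deleted untreated and 36120808 to 44133028 in deleted PRL libraries. Chi-square per degree of freedom between replicate libraries was 51.17 to 212.3 over the genes above a minimum summed count in the pair. This value says nothing about single genes with few counts. The median half-width of the 95% interval of a log2 fold change was 0.688 and 0.687 for the PRL effects, 0.686 and 0.688 for the deletion effects, 0.486 for each average and 0.971 for the interaction.

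Analysis used R 4.3.3. Genes were kept by filterByExpr (17677), scaled by TMM and fitted in edgeR 4.0.16 with 1 mean per group, no covariate and robust quasi-likelihood dispersions (8 residual degrees of freedom, biological coefficient of variation 0.303). Each of 7 contrasts was tested with the quasi-likelihood F test, adjusted over all tested genes by Benjamini-Hochberg and called at 0.05. Standard errors are the fold change divided by the square root of F. CPM are TMM-scaled, and log values for components use a prior count of 2. The 31 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01), camera with an estimated correlation and fry, adjusted over the lists within a contrast, and members were also adjusted over the list alone. Adjusted p-values beside a list median are camera's with the preset correlation unless named otherwise. The response size was the median interaction over genes called for the averaged PRL effect, signed by that effect, and needed at least 10 genes. Coordinates, GC content and transcript length came from GENCODE 29, whose GC covered 96.45% of tested genes.

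Groups, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. Named were PRLR and its pathway genes; per contrast the 10 genes with the largest rise and the 10 with the largest fall among those called, with a mean of at least 1 CPM, a gene symbol and no overlap between groups; the 4 members with the smallest p of each list with called members; and the 5 smallest p where fewer than 5 genes were called. BCOR, HEG1, TLE3, TFEB, ABTB2 and other genes called outside the 10, members called over a list alone, and the overlapping partners were named after their values were seen.

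Alternatives were RLE, upper-quartile and library-size scaling, no count filter and a stricter one (at least 1 CPM and 10 counts in 3 libraries), DESeq2 1.42.0, limma-voom with quality weights, dispersions without robust estimation, fits of the compared groups only, 1 surrogate variable from sva 3.50.0, leaving out PRLR and the 10 genes with the highest counts, a log2 fold change of at least 1 and leaving out each library. A term for runs of title numbers, a GC and length offset, leaving out 2 libraries together, and surrogate and upper-quartile settings for the lists were added after the data were seen.

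The method was tested on simulated data with the spread of these libraries. Counts were drawn independently for each gene, without structure shared between genes or libraries. Changed genes had a mean of at least 1 CPM, so recovery of genes with lower counts was not tested. For the averaged PRL effect the method recovered 98.51% of genes changed 4-fold, 56.72% at 2-fold and 13.64% at 1.5-fold, with 7 false calls in 17196 genes. For the interaction it recovered 73.13%, 2.985% and 0%, with 1 false call in 17222. A simulated list of 25 genes changed 1.5-fold was called, and 0 of 20 random lists were. Simulated genes were uncorrelated, so this does not show how often the preset test falsely calls correlated lists. In the measured data the estimated correlation of the G2-M list was 0.682 for the averaged PRL effect. Reads, isoforms and the receptor's I-tail sequence were not analysed here, since the table gives gene counts only.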

Results

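MCF10AT cells, a Ras-transformed line derived from MCF10A human breast epithelial cells, expressed the long prolactin receptor together with the intermediate receptor (hPRLrL/hPRLrI). In a second set of cells the I-tail of the intermediate receptor was deleted. After 24 h without serum, cells were left untreated or received prolactin (PRL) at 250 ng/ml for 2 h, and polyA RNA was sequenced. The table holds 12 libraries, 3 in each of 4 groups, with 36120808 to 57324865 counts per library, and libraries are numbered 1 to 3 within each group in the order of their titles. Of its genes, 17677 entered the tests. PRL effects were estimated in each receptor pair and as their average, deletion effects in each treatment and as their average, and the interaction compared the 2 PRL effects.

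PRLR, the gene of the altered receptor (ENSG00000113494, GRCh38 chromosome 5, 35048756 to 35230589 in GENCODE 29), was among the abundant transcripts in all 12 libraries. Its mean ± SD was 3405 ± 160 CPM (counts scaled to a common library size) in intact untreated cells, 3650 ± 478 with PRL, 3581 ± 110 in deleted untreated cells and 3551 ± 362 with PRL (n = 3 each). The averaged log2 fold change was 0.04 ± 0.12 (SE) for PRL and 0.02 ± 0.12 for the deletion (edgeR quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.983 and 0.993). A gene count does not separate the receptor isoforms and does not show the I-tail. Of the receptor's signalling partners named here, none passed the test after PRL: STAT5A stood at -0.09, STAT5B at -0.04, STAT3 at 0.08, JAK1 at -0.09, JAK2 at -0.10, HRAS at 0.24, EGFR at -0.03, ERBB2 at 0.17 and SRC at 0.52 ± 0.23 (adjusted p = 0.98). SOCS1 stood at 0.32 and SOCS3 at -0.07.

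**Figure D1:**
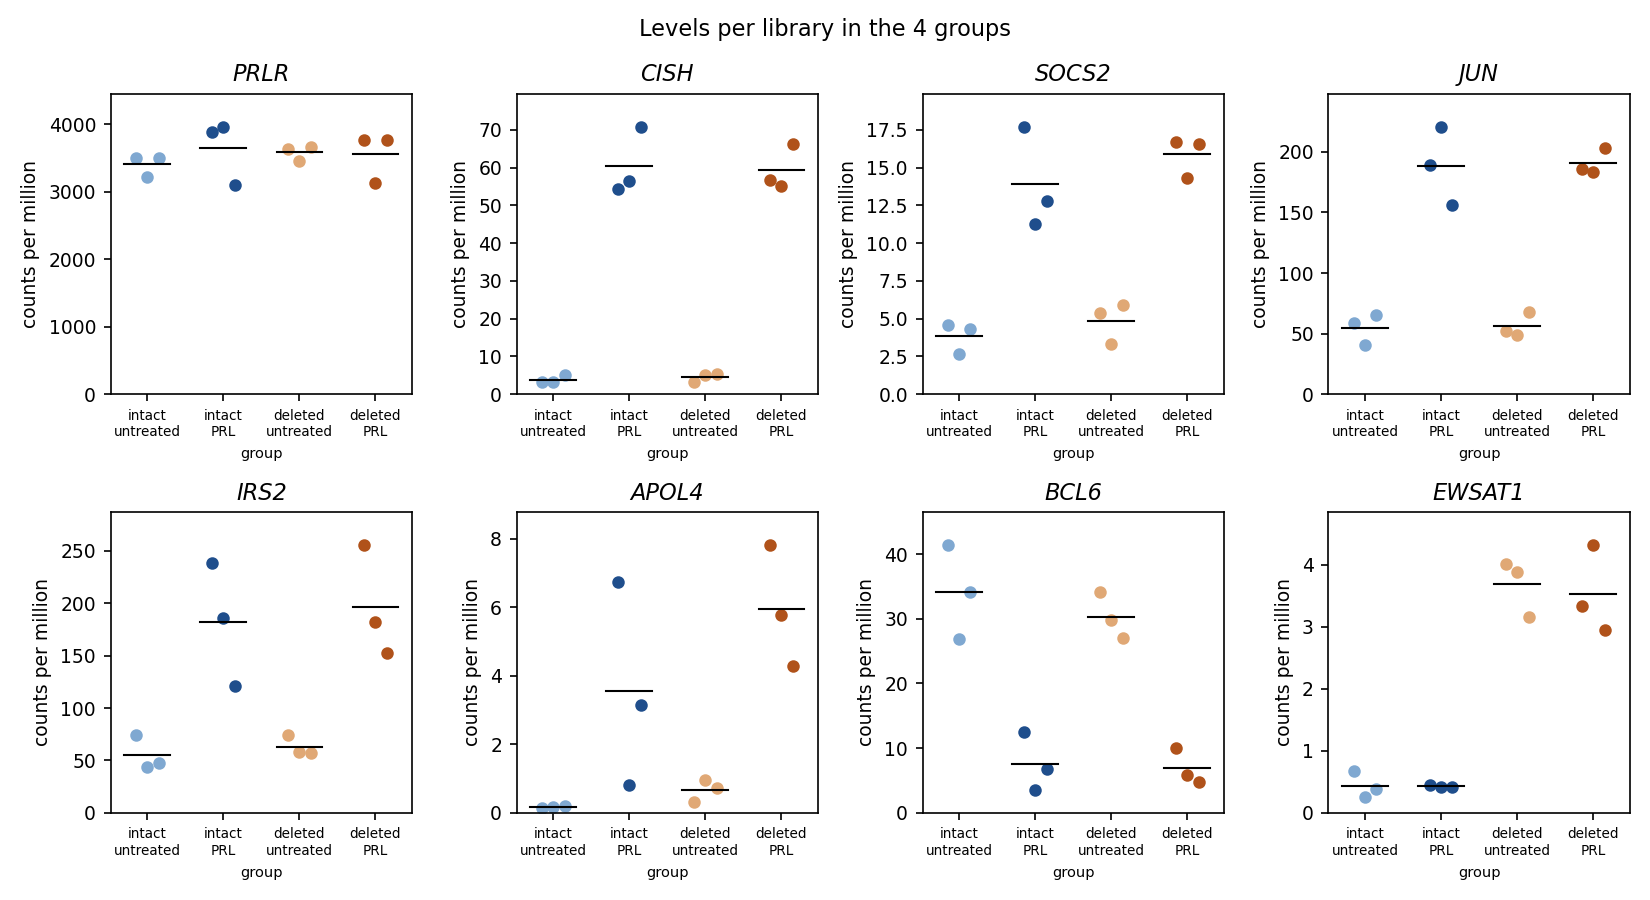
CPM of 8 genes in each of the 12 libraries, with group means as lines. PRLR is the altered receptor.

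PRL raised CISH, a cytokine-inducible feedback inhibitor of STAT5 signalling, 14.3-fold on average over both receptor pairs (log2 3.84 ± 0.18, adjusted p = 1.45e-07, higher in 6 of 6 treated libraries). Its level went from 3.83 ± 0.99 to 60.5 ± 8.95 CPM with the intact I-tail and from 4.57 ± 1.14 to 59.4 ± 6.11 CPM with the deleted one (n = 3 each). SOCS2, a second feedback inhibitor of cytokine receptors, rose by 1.78 ± 0.20 (adjusted p = 0.00213). BCL6, a transcriptional repressor that competes with STAT5 for DNA sites, fell 4.45-fold (-2.15 ± 0.27, adjusted p = 0.00477), from 34.2 ± 7.20 to 7.60 ± 4.51 CPM and from 30.3 ± 3.55 to 6.86 ± 2.73 CPM. IRS2, an adaptor of insulin and cytokine receptors, rose by 1.68 ± 0.20 (adjusted p = 0.00383), from 55.2 to 181.9 CPM and from 63.1 to 196.6 CPM.

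Among 21 genes called for this average, 20 rose and 1, BCL6, fell. JUN, an AP-1 subunit, rose by 1.77 ± 0.15 (adjusted p = 2.08e-04), and its relative JUNB by 0.94 ± 0.16 (adjusted p = 0.0386). IL11, a cytokine of the IL-6 family, rose by 1.52 ± 0.22 (adjusted p = 0.0108). The nuclear receptor genes RARA (1.30 ± 0.20, adjusted p = 0.0203) and VDR (1.09 ± 0.16, adjusted p = 0.0151) rose, as did 2 inhibitors of SMAD signalling, SMAD6 (1.13 ± 0.15, adjusted p = 0.00663) and SKI (0.97 ± 0.13, adjusted p = 0.00477). The pseudokinase gene TRIB1 rose by 1.09 ± 0.15 (adjusted p = 0.00694) and the ankyrin-repeat gene SOWAHC by 1.52 ± 0.14 (adjusted p = 3.14e-04). APOL4, an apolipoprotein L gene near the detection limit in untreated cells, rose by 3.75 ± 0.46 (adjusted p = 0.00383), from 0.171 ± 0.0349 to 3.56 ± 2.99 CPM and from 0.667 ± 0.318 to 5.95 ± 1.77 CPM. The transcription factor FOXC2 (1.08) and the exchange factor DNMBP (0.98) rose, and BCOR (0.88), HEG1 (0.86), TLE3 (0.77), TFEB (0.76) and ABTB2 (0.67) rose with adjusted p from 0.0345 to 0.047.

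In GENCODE 29 coordinates (GRCh38), CISH (ENSG00000114737) lies on chromosome 3 at 50606490 to 50611831, BCL6 (ENSG00000113916) on chromosome 3 at 187721377 to 187745727, JUN (ENSG00000177606) on chromosome 1 at 58780788 to 58784327 and SOCS2 (ENSG00000120833) on chromosome 12 at 93569814 to 93583487. IRS2 (ENSG00000185950) lies on chromosome 13 at 109752698 to 109786568, IL11 (ENSG00000095752) on chromosome 19 at 55364389 to 55370463, SOWAHC (ENSG00000198142) on chromosome 2 at 109614334 to 109618990 and APOL4 (ENSG00000100336) on chromosome 22 at 36189124 to 36204840. CISH, SOCS2, RARA, VDR, JUNB and FOXC2 overlap measured genes on the opposite strand. The strand setting of the counting is not given in the sources used here, so reads of a gene and its overlapping partner cannot be told apart. The partners were not called: MAPKAPK3 beside CISH stood at 0.29 ± 0.21, SOCS2-AS1 at 0.71 ± 0.24, RARA-AS1 at 0.61 ± 0.28, HOOK2 beside JUNB at 0.10 ± 0.13 and FOXC2-AS1 at 0.39 ± 0.64 (adjusted p = 0.94 to 0.98), and ENSG00000278385 in VDR stood at -0.20 ± 0.59 (adjusted p = 0.984).

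The count of 21 was 12 without deleted untreated library 1 and 11 without deleted untreated library 2. Calls of CISH, JUN, SOWAHC, SOCS2, IRS2, DNMBP, APOL4, BCL6, SKI, SMAD6 and TRIB1 held in all 12 leave-outs of 1 library. Those of IL11 and VDR ended without deleted untreated library 1 or 2 (adjusted p up to 0.0571), and that of FOXC2 without deleted untreated library 2 (0.0571). That of RARA ended without deleted untreated library 1, 2 or 3, deleted PRL library 2 or 3 or intact untreated library 3 (up to 0.0928). HEG1 lost its call in 8 leave-outs, all but those of intact PRL libraries 1 to 3 and deleted PRL library 3 (up to 0.187). TLE3 lost it in 9, all but those of intact PRL libraries 1 to 3 (up to 0.172), and BCOR in 9, all but those of intact PRL libraries 1 and 3 and deleted PRL library 3 (up to 0.169). JUNB lost it in 10, all but those of intact PRL libraries 1 and 2 (up to 0.187), TFEB in 10, all but those of intact PRL library 1 and intact untreated library 2 (up to 0.214), and ABTB2 in 11, all but that of intact PRL library 1 (up to 0.187). Scaling by library size alone ended the calls of TRIB1 (adjusted p = 0.197), FOXC2 (0.109), HEG1 (0.441), BCOR (0.351) and ABTB2 (0.153), and RLE scaling those of TFEB (0.0988), TLE3 (0.0571), JUNB (0.0807) and ABTB2 (0.0571). An offset for GC content and length ended those of IRS2 (0.054), FOXC2 (0.143) and ABTB2 (0.0838). These losses are not all: of 25 alternative settings, leave-outs included, VDR kept its call in 22, FOXC2 in 21 and HEG1 in 15. BCOR and TLE3 kept theirs in 14, TFEB and JUNB in 13 and ABTB2 in 10. The count of 21 was 91 with DESeq2, 116 with limma-voom, 124 without a count filter, 160 with 1 surrogate variable, 198 with a term for runs of title numbers, 62 with the GC and length offset and 13 at a log2 fold change of at least 1, and all but the last 2 kept all 21 genes.

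By the gene lists fixed in advance, PRL shifted 4 lists upward under camera with a preset correlation, camera with an estimated correlation and fry alike. Of 18 measured JAK2-STAT5 targets, CISH and SOCS2 rose, BCL6 fell and 15 did not pass, with the same counts adjusted over the list alone (median 0.12, preset adjusted p = 1.8e-09). In the 19 STAT3 and cytokine feedback genes, IL11 and JUNB rose over all genes, and CEBPB, a transcription factor of cytokine responses, also rose adjusted over the list alone (0.48 ± 0.13, adjusted p = 0.0161). That list's median of 0.06 (preset adjusted p = 2.62e-04) turned to -0.04 when scaled by library size alone, while the test stayed upward. Of 30 immediate early genes, 2 rose over all genes, and 7 rose and 1 fell adjusted over the list alone (median 0.15, preset adjusted p = 3.32e-06), among them KLF6 (0.64 ± 0.13), the orphan receptor gene NR4A3 (1.08 ± 0.29) and NR4A2, which fell (-1.03 ± 0.27). TGF-beta targets had the largest median of these 4 lists, 0.40, with 22 of 24 members above 0 (preset adjusted p = 2.15e-18). SMAD6 was called over all genes, and 9 members rose adjusted over the list alone, among them SMAD7, an inhibitory SMAD (0.75 ± 0.16), the adhesion adaptor NEDD9 (1.25 ± 0.26) and ID2, an inhibitor of DNA binding (0.94 ± 0.21). With an estimated correlation each of the 4 lists had adjusted p = 0.0274, and with fry 0.0367. The 4 calls held in all leave-outs of 1 library, over which the medians ran from 0.06 to 0.21 for JAK2-STAT5 targets, 0.02 to 0.09 for STAT3 and cytokine feedback genes, 0.05 to 0.29 for immediate early genes and 0.25 to 0.52 for TGF-beta targets.

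Ras-MAPK activity genes did not pass over all genes, and adjusted over the list alone 5 of 24 rose and 1 fell. HBEGF and AREG, both ligands of the EGF receptor, rose by 1.10 ± 0.26 and 0.52 ± 0.17, the AP-1 gene FOSL1 by 1.22 ± 0.34 and IER3 by 0.73 ± 0.14, and SPRY4, a feedback inhibitor of this pathway, by 0.91 ± 0.29, while its relative SPRY1 fell (-0.83 ± 0.28). The list's median was 0.16 (preset adjusted p = 6.42e-05, adjusted p = 0.174 with an estimated correlation). PI3K-AKT-FOXO targets moved both ways: over all genes IRS2 and TRIB1 rose and BCL6 fell, and adjusted over the list alone KLF6 and TRIB3 (1.08 ± 0.28) also rose and CITED2 (-0.49 ± 0.11) and SESN1 (-0.51 ± 0.18) also fell. That list had a median of -0.24, a preset adjusted p = 0.512 in 1 direction and, by fry in either direction, adjusted p = 2.35e-06.

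A further 6 lists passed the preset test and were lost with an estimated correlation. Medians were 0.31 for G2-M and mitosis (adjusted p = 0.00108, 0.697 with an estimated correlation), 0.16 for YAP-TAZ targets (0.00782, 0.416), 0.20 for cholesterol synthesis (0.0136, 0.593), -0.13 for p53 targets (0.0136, 0.593), -0.22 for replication-dependent histones (0.0425, 0.416) and 0.28 for leukocyte markers (0.0136, 0.11). The G2-M median was -0.0448 without intact PRL library 2, the library with the fewest detected genes (19073), and its call also ended without intact untreated library 3 (0.22). Leave-outs also ended the calls of cholesterol synthesis (0.06 without intact PRL library 2, 0.20 without deleted untreated library 2, 0.13 without deleted PRL library 3), p53 targets (-0.15 without intact PRL library 1, -0.17 without deleted PRL library 1, -0.09 without intact untreated library 3) and YAP-TAZ targets (0.09 without intact PRL library 2). Those of leukocyte markers ended without deleted PRL library 1 (0.26) or deleted untreated library 2 (0.30), and those of histones without intact PRL library 1 or 2, deleted untreated library 1, intact untreated library 2 or 3 or deleted PRL library 2 or 3 (-0.26 to -0.16). The count of 11 lists was 7 without intact PRL library 2. With 1 surrogate variable the G2-M (0.14), cholesterol (0.08) and YAP-TAZ (0.04) calls ended, with library size alone (-0.31) or the title-run term (-0.23) the histone call, and with the GC and length offset the leukocyte call (0.29). In the leukocyte list only CD14, which epithelial cells also express, rose adjusted over the list alone (0.64 ± 0.17). The other lists did not pass in 1 direction. Medians were 0.12 for G1-S, -0.02 for the interferon response, -0.03 for TNF and NF-kB genes, 0.08 for hypoxia, 0.05 for the unfolded protein response, -0.06 for heat shock, -0.01 for mesenchymal genes (mean 0.01 with an upward test, and a median of 0.01 with RLE scaling), -0.04 for epithelial junctions, 0.06 for basal and 0.09 for luminal markers. Milk protein genes had a median of -0.04 and a mean of 0.01 with an upward test. Medians were 0.21 for epidermal differentiation, -0.08 for stem and progenitor genes, 0.01 for matrix proteases, 0.01 for mitochondrial mRNAs, 0.05 for ribosomal proteins, -0.03 for fibroblast markers and 0.16 for endothelial markers. WNT and Notch targets had a median of 0.05 and a mean of -0.12 with a downward test (adjusted p = 0.19). By fry in either direction this list passed (adjusted p = 0.0156), and HES1 and DLL1 fell adjusted over the list alone. Library size alone shifted the median of all genes by -0.10 for this average. It turned below 0 the medians of the hypoxia, unfolded protein, basal, luminal, WNT and Notch, protease, mitochondrial and ribosomal lists. Upper-quartile scaling did so for the protease and mitochondrial lists. None of these lists was called by the preset test.

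**Figure D2:**
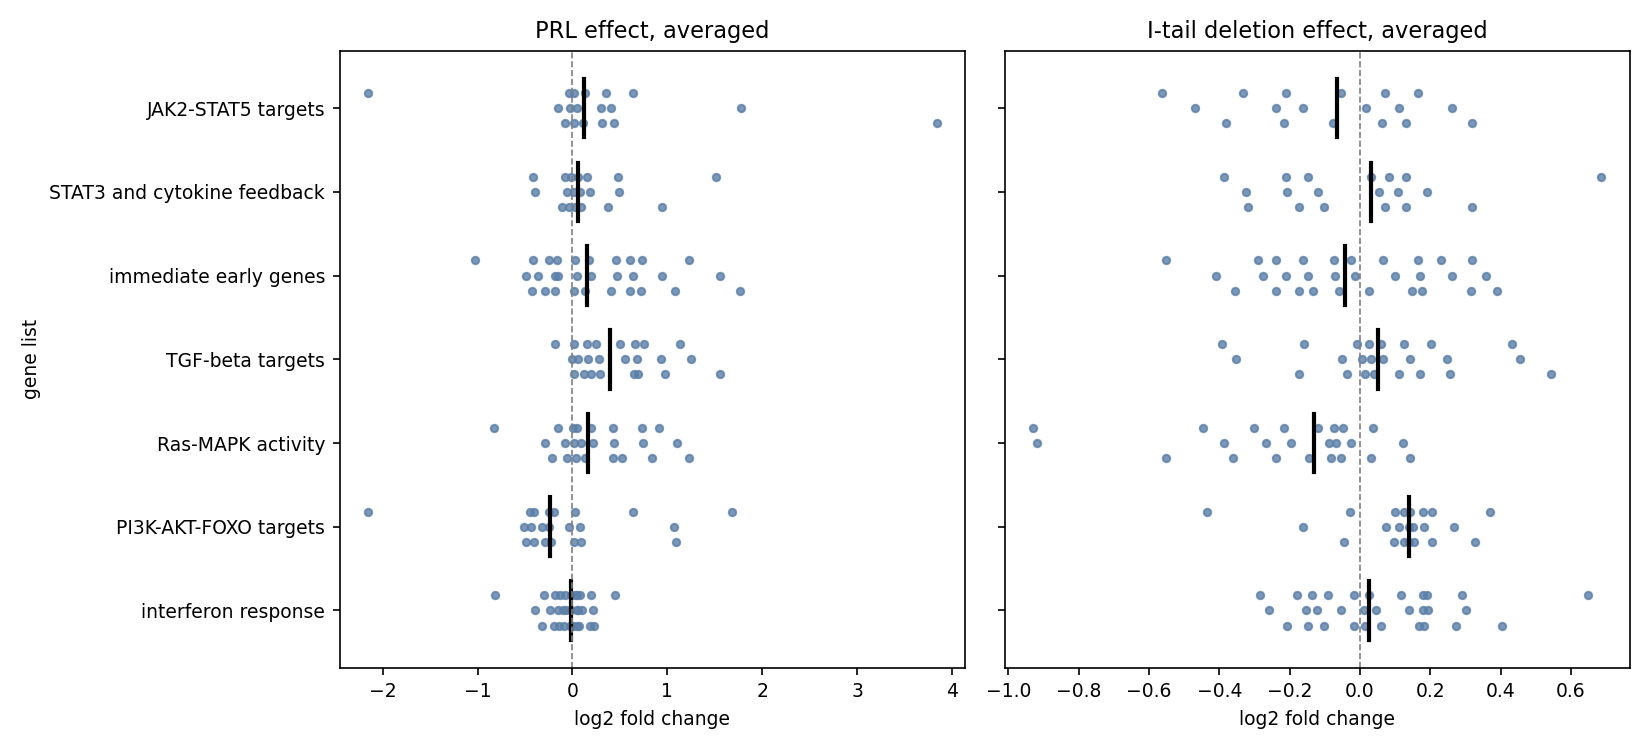
Log2 fold changes of the members of 7 gene lists for the averaged PRL and averaged deletion effects. Black bars are list medians. Scaled by library size alone, the PRL median of the STAT3 list turned below 0 and the deletion medians of the JAK2-STAT5 and immediate early lists above 0, and with RLE scaling the deletion median of the interferon list below 0.

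With the intact I-tail alone, PRL raised CISH (3.98 ± 0.25, adjusted p = 8.8e-06), JUN (1.78 ± 0.22, adjusted p = 0.0101) and SOWAHC (1.61 ± 0.20, adjusted p = 0.0101). SOCS2 (1.85 ± 0.28, adjusted p = 0.0668), DNMBP (1.10 ± 0.17, adjusted p = 0.0681), IRS2 (1.72 ± 0.29, adjusted p = 0.0972) and BCL6 (-2.16 ± 0.39, adjusted p = 0.153) did not pass. With the I-tail deleted, the same 3 genes rose: CISH by 3.70 ± 0.25 (adjusted p = 1.84e-05), JUN by 1.76 ± 0.22 (adjusted p = 0.0134) and SOWAHC by 1.43 ± 0.20 (adjusted p = 0.0342). Chance gives 0.000509 shared genes for independent comparisons, but both use 1 shared estimate of the spread per gene. SOCS2 (1.71 ± 0.28, adjusted p = 0.139), IRS2 (1.64 ± 0.29, adjusted p = 0.215) and BCL6 (-2.14 ± 0.39, adjusted p = 0.249) did not pass with the I-tail deleted. At unadjusted p under 0.05 there were 451 and 316 genes.

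CISH held in all leave-outs of both receptor pairs. With the intact I-tail, 1 gene was left without intact untreated library 2 or 3, where the calls of JUN (adjusted p up to 0.0529) and SOWAHC (up to 0.104) ended. SOWAHC also lost its call without intact untreated library 1 (0.0552) or intact PRL library 3 (0.0588). With the deleted I-tail, 1 gene was left without deleted untreated library 1 or 2 or deleted PRL library 2 or 3, each of which ended the calls of JUN (up to 0.237) and SOWAHC (up to 0.461), and 5 genes were called without intact PRL library 2. SOWAHC also lost its call there without deleted untreated library 3, deleted PRL library 1, intact untreated library 3 or intact PRL library 3 (0.0798 or above). Library size alone ended the calls of JUN and SOWAHC in both pairs (adjusted p = 0.12 and 0.249 intact, 0.0917 and 0.379 deleted), and a fit of the compared groups only ended both with the intact I-tail (0.398 each). Counts with the intact and deleted I-tail were 22 and 20 with DESeq2, 25 and 21 with limma-voom, 46 and 33 without a count filter, 52 and 46 with 1 surrogate variable, 62 and 57 with the title-run term and 11 and 15 with the GC and length offset.

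With the intact I-tail the preset test called 10 lists, among them TGF-beta targets (median 0.50, 23 of 24 above 0, adjusted p = 2.26e-15), immediate early genes (0.31, adjusted p = 5.65e-05) and JAK2-STAT5 targets (0.16, adjusted p = 2.09e-08). With the deleted I-tail it called 9 lists, among them TGF-beta targets (0.29, adjusted p = 1.85e-10), JAK2-STAT5 targets (0.05, adjusted p = 2.92e-05) and immediate early genes (0.03, adjusted p = 4.34e-04). Library size alone turned the deleted-pair medians of the last 2 lists to -0.03 and -0.05 while the test stayed upward. In neither pair did a list pass with an estimated correlation, where TGF-beta targets had adjusted p = 0.0687 and 0.105. These 6 calls held in all leave-outs, and without intact untreated library 1 the count with the intact I-tail was 6 lists. Over the leave-outs, medians with the intact I-tail ran from 0.40 to 0.69 for TGF-beta targets, 0.10 to 0.48 for immediate early genes and 0.04 to 0.34 for JAK2-STAT5 targets. With the deleted I-tail they ran from 0.20 to 0.54, -0.05 to 0.29 and 0.04 to 0.18.

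The PRL response did not differ between the receptor pairs for any gene by the interaction test. The differences of the 2 PRL effects were -0.28 ± 0.32 for CISH, -0.14 ± 0.38 for SOCS2, -0.02 for JUN, 0.02 for BCL6 and -1.20 for APOL4 (adjusted p = 1). The test called 0 genes, as did DESeq2 and limma-voom, with 127 genes at unadjusted p under 0.05. The smallest p-values belonged to ENSG00000223461, PMS2P3 (ENSG00000291092), AURKC, PPIAP43 and ADH1B, of which AURKC, a meiotic kinase gene, stood at 1.96 ± 0.52 and PMS2P3 at -1.99 ± 0.52 (adjusted p = 1). Over the 21 genes called for the average, the median difference signed by direction was -0.04, with 14 genes smaller and 7 larger with the deletion. That median ran from -0.192 without deleted PRL library 3 to 0.0712 without intact PRL library 2, so its sign is not settled. Median signed responses were 1.11 and 1.10, and fry on the difference gave p = 0.517 (n = 12). The median of the 95% interval half-widths of the differences was 0.97, so smaller differences between the pairs are not excluded. Larger ones are not excluded for genes with wider intervals. A missing call decides little, since the interaction test recovered 2.985% of simulated 2-fold and 73.13% of simulated 4-fold differences.

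**Figure D3:**
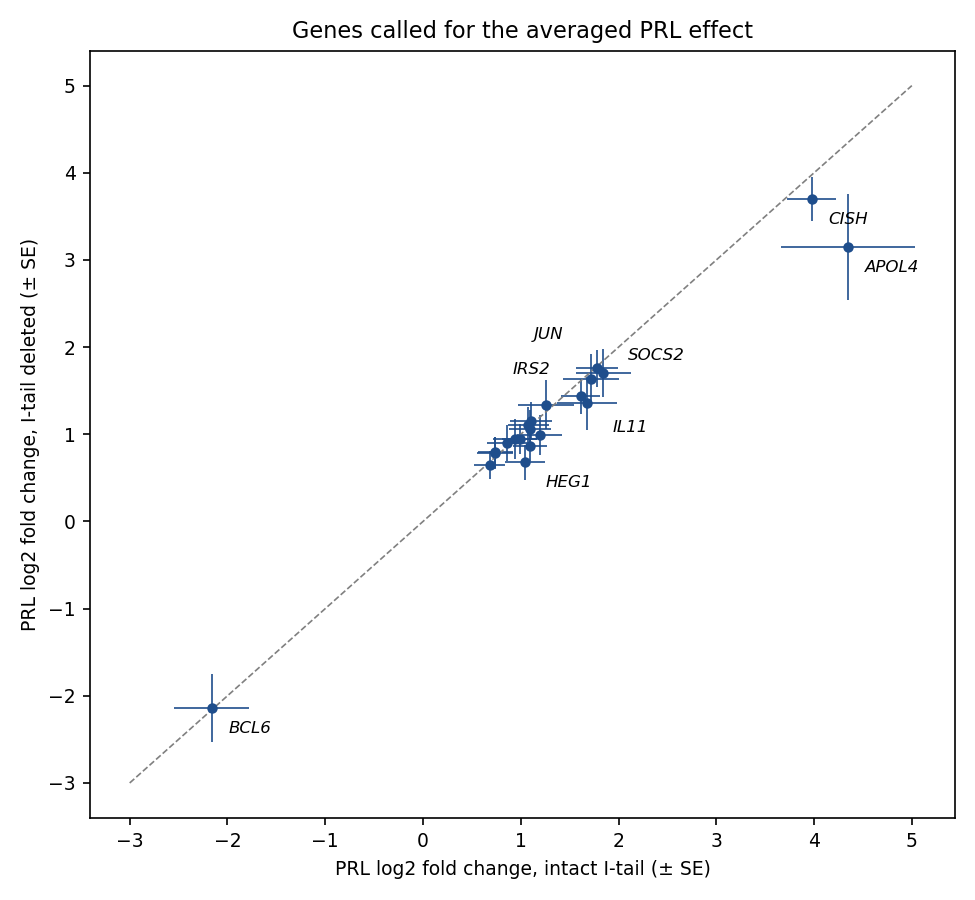
PRL log2 fold changes of the 21 called genes with the intact and the deleted I-tail, with standard errors. The dashed line marks equal responses.

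By list, the interaction test called 2 lists with the preset correlation. G2-M genes had a median difference of 0.26 with 23 of 30 above 0, and ribosomal protein genes 0.15 with 48 of 48 above 0. Both had adjusted p = 7.7e-05, against 0.739 with an estimated correlation and 0.956 with fry. The G2-M call ended without intact untreated library 2 (median -0.15) or intact PRL library 3 (0.01), and over all leave-outs the median ran from -0.15 to 0.98 (without intact PRL library 2). It was 0.47 with the title-run term and 0.55 without both intact libraries 2, called by the preset test in both. The ribosomal call ended without intact PRL library 1 (0.09) or intact untreated library 2 (0.08), and over all leave-outs the median ran from 0.08 to 0.31. Intact untreated library 2 and intact PRL library 2 had 19905 and 19073 detected genes, the fewest of the 12. The count of called lists was 7 without intact PRL library 1, 12 without deleted untreated library 1, 1 without intact untreated library 2, 4 without intact PRL library 2 or deleted PRL library 2, and 11 without intact untreated library 3 or deleted PRL library 3.

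Deletion of the I-tail went with a higher level of EWSAT1, a long noncoding RNA gene (ENSG00000212766, chromosome 15, 69072926 to 69095820), in untreated and in PRL-treated cells. Its mean was 0.434 ± 0.217 and 0.429 ± 0.0214 CPM in the intact groups and 3.69 ± 0.465 and 3.53 ± 0.705 CPM in the deleted groups (n = 3 each), 8.29-fold on average (log2 3.05 ± 0.25, adjusted p = 1.82e-04, higher in 6 of 6 libraries). It was called in untreated cells (3.07 ± 0.35, adjusted p = 0.0105) and in PRL-treated cells (3.03 ± 0.35, adjusted p = 0.0135). Chance gives 5.66e-05 shared genes for independent comparisons, but both compare the same 2 sets of cells. Any fixed difference between these sets recurs in both treatments, so the repeat is not independent support. No other gene passed, with 148 and 286 genes at unadjusted p under 0.05 and 403 for the average. Nearest to the threshold were GIMAP6, a GTPase gene of the immunity-associated family (2.69 ± 0.38), MB, which encodes myoglobin (-1.95 ± 0.29), and ENSG00000287458 (-2.62 ± 0.39), all with adjusted p = 0.0562. MUC17, a membrane mucin gene, had no count in any of the 6 deleted libraries, against 72 counts in the 3 intact untreated ones and 35 with PRL. Setting the empty group to a floor of 3 counts over the group puts it 4.56 and 3.55 log2 units lower (adjusted p = 1 in both). LTF, the milk protein lactoferrin, had no count in any intact library, against 47 counts in the deleted untreated ones and 16 with PRL. The same floor puts it 3.99 and 2.41 log2 units higher (adjusted p = 1 in both). These floor values for MUC17 and LTF leave out the spread between libraries and the error of the few counts, so they are not bounds.

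The averaged EWSAT1 call held in all leave-outs. In untreated cells it ended without deleted untreated library 1 or 2 or intact untreated library 2 or 3 (adjusted p = 0.0645 to 0.246), so no gene was called there. In PRL-treated cells it ended without intact PRL library 1, 2 or 3 or deleted PRL library 1 or 2 (0.0503 to 0.281), again with no gene called. The averaged count was 2 without intact untreated library 1. CISH (0.11 ± 0.16), SOCS2 (0.26 ± 0.19), STAT5A (-0.25 ± 0.14), EGFR (0.20 ± 0.11) and HRAS (-0.29 ± 0.22) were not called for the averaged deletion effect (adjusted p = 0.991). The call in untreated and in PRL-treated cells also ended with library size alone (0.135 and 0.13) and with the compared groups only (0.291 and 0.0909). The averaged count was 10 with DESeq2, 8 with limma-voom, 33 without a count filter, 4 with 1 surrogate variable, 11 with the title-run term and 3 with the GC and length offset, and EWSAT1 was among them each time.

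No list passed for the deletion with an estimated correlation (adjusted p = 0.665 for each of the 8 named here) or with fry in 1 direction, and the preset test called 8 for the average. Ras-MAPK activity genes stood lower with the deletion (median -0.13, 20 of 24 below 0, adjusted p = 0.00183), as did mitochondrial mRNAs (-0.20, 13 of 13 below 0, adjusted p = 3.16e-06) and leukocyte markers (-0.45, adjusted p = 0.0497). Basal markers (0.31, 20 of 22 above 0, adjusted p = 0.0105), epithelial junction genes (0.26, 22 of 29, adjusted p = 0.0123), stem and progenitor genes (0.21, adjusted p = 0.0276), PI3K-AKT-FOXO targets (0.14, adjusted p = 0.0286) and ribosomal proteins (0.13, adjusted p = 0.00216) stood higher. Of the milk protein genes LTF alone passed adjusted over the list alone, and fry in either direction gave adjusted p = 0.00507. The Ras-MAPK median was -0.08 in untreated cells (preset adjusted p = 0.0271, adjusted p = 0.601 with an estimated correlation) and -0.18 in PRL-treated cells (0.00383 and 0.595).

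Over the leave-outs for the averaged deletion effect, the mitochondrial mRNAs kept their call in all 12 (median -0.26 to -0.14), and the Ras-MAPK call ended without deleted PRL library 3 (-0.12). That of the epithelial junction genes ended without intact untreated library 1, intact PRL library 1, deleted untreated library 3 or deleted PRL library 3 (adjusted p up to 0.569), and that of the basal markers without those or deleted untreated library 2 (up to 0.521). That of the stem and progenitor genes ended without library 1 or 2 of either intact group, deleted untreated library 3 or deleted PRL library 3 (up to 0.261). Ribosomal proteins lost theirs without intact untreated library 1, intact PRL library 1, deleted untreated library 2 or deleted PRL library 2 or 3 (up to 0.26). PI3K-AKT-FOXO targets lost theirs without library 1 or 2 of the intact untreated group, intact PRL library 2, deleted untreated library 1 or 3 or deleted PRL library 1 or 3 (up to 0.357). Leukocyte markers lost theirs in 9 leave-outs, all but those of intact untreated library 2, deleted untreated library 1 and deleted PRL library 1 (up to 0.2), and with RLE (0.0565) or upper-quartile scaling (0.0573), the title-run term (0.0973), the GC and length offset (0.182) or 1 surrogate variable (0.103). The GC and length offset also ended the PI3K-AKT-FOXO (0.147) and stem and progenitor calls (0.147), and 1 surrogate variable the PI3K-AKT-FOXO call (0.293) and the Ras-MAPK call in untreated cells (0.108). The Ras-MAPK call in untreated cells ended without intact untreated library 2 or 3 or deleted untreated library 1 or 3 (up to 0.448), and in PRL-treated cells without intact PRL library 2 (-0.07) or deleted PRL library 3 (-0.17). The averaged count of 8 lists was 2 without intact untreated library 1, 3 without intact PRL library 1 or deleted untreated library 3, and 1 without deleted PRL library 3. The count of 9 lists in untreated cells was 3 and 5 without intact untreated library 1 and 2, not all of them among the 9, and none was called without deleted untreated library 3. Of 3 lists in PRL-treated cells, the count was 6 without deleted PRL library 1 and 10 without intact PRL library 3.

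Libraries differed along a main axis that crossed the groups. The first principal component held 35.37% of the variance and followed each library's relation of deviation to GC content (Pearson r = 0.937, Spearman rho = 0.965, permutation p = 1e-05, the smallest these permutations can give, n = 12). It also followed the number of detected genes (r = -0.939, rho = -0.958, permutation p = 1e-05, n = 12). Without the 2 farthest libraries r was 0.923 and -0.863. The first libraries of the 4 groups scored -54.74 to -40.42 on this component, and all others -10.54 to 94.26. Component and relations come from the same counts, and the permutations treat libraries as exchangeable. They therefore describe the axis without naming its cause. Detected genes averaged 22980 ± 2749 and 21770 ± 2702 (SD) in the intact groups and 23993 ± 927 and 22928 ± 1879 in the deleted groups. All genes with a symbol starting with MT-, not only the listed mitochondrial mRNAs, made up 12.4 ± 1.93, 12.1 ± 1.38, 12.1 ± 1.81 and 11.1 ± 0.995 percent of counts. The 2 relations shown are the only ones tested.

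**Figure D4:**
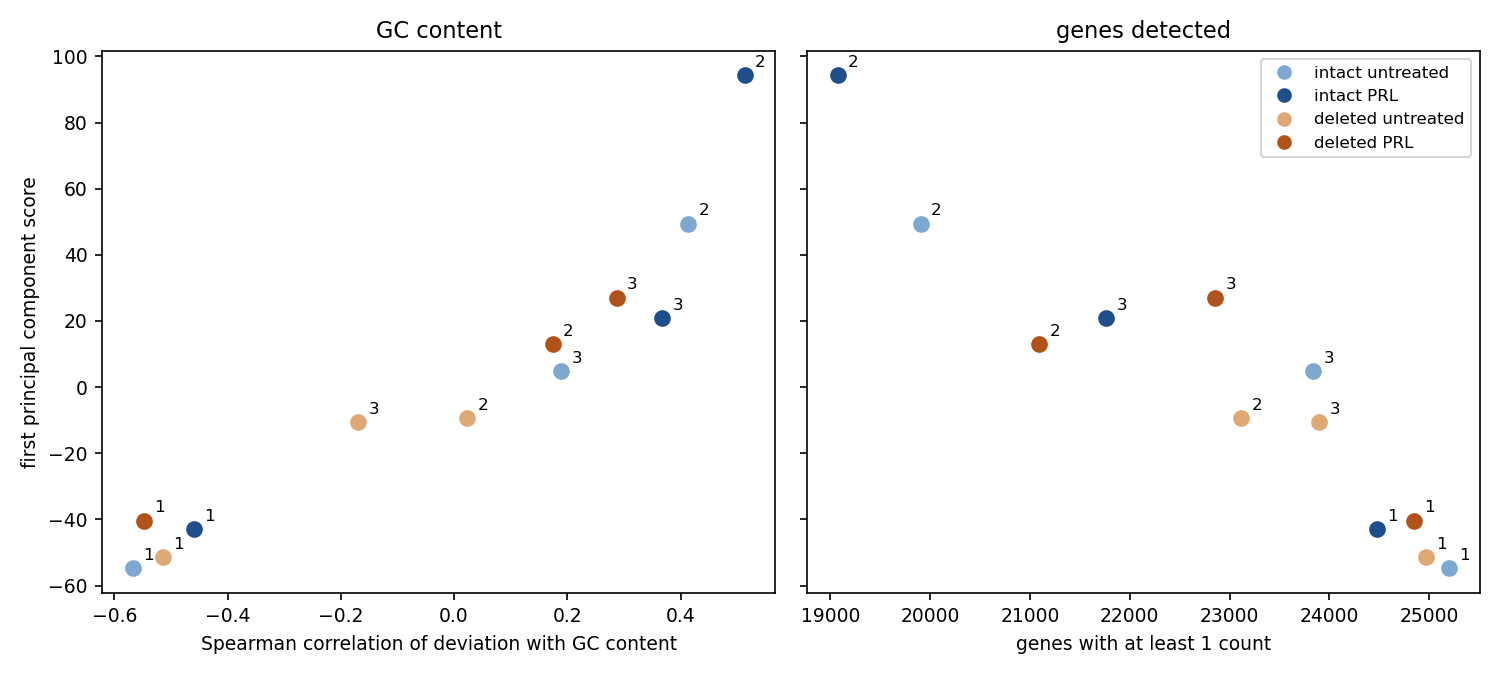
First principal component score of each library against its relation to GC content and its number of detected genes. Numbers are replicate numbers and colours are groups.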

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

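For the 2 list patterns here, the GC and length offset, the run term, leaving out both second intact libraries and the use of the leave-outs to weigh single libraries were chosen only after the result was seen, while the list tests and the leave-outs of 1 library were planned.

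AURKC, a meiotic kinase gene, had an interaction log2 fold change of 1.96 ± 0.52: all 3 PRL libraries lay below all 3 untreated ones with the intact I-tail (1.18 ± 0.312 to 0.519 ± 0.0413 CPM) and above them with the deleted one (0.772 ± 0.279 to 1.34 ± 0.131 CPM). PPIAP43, a processed pseudogene, showed the same opposite movement, 5.39 ± 1.45 as fitted from few counts (0.299 to 0.0144 and 0.0938 to 0.259 CPM). The difference was tested for both genes and did not pass (edgeR, adjusted p = 1). Opposite movement was looked for only among genes already named for the interaction, where both stood for their small p among 17677 genes. How many of all genes move this way, by chance or not, was not counted.

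The median difference in PRL effect, deleted minus intact I-tail, was 0.26 for the G2-M list and 0.15 for the ribosomal protein list. Only the preset test called these differences: adjusted p was 7.7e-05, against 0.739 with an estimated correlation and 0.956 with fry. G2-M medians were 0.21 (intact, adjusted p = 0.72) and 0.53 (deleted), and ribosomal medians -0.02 (intact, adjusted p = 0.547) and 0.15 (deleted). A trend of GC content and length does not account for the whole of either difference: with an offset for both, 1.01 of the G2-M median (0.263) and 0.778 of the ribosomal median (0.119) remained. The differences may rest on single libraries, since 2 of 12 leave-outs ended the G2-M call (median -0.152 without the second intact untreated and 0.0117 without the third intact PRL library) and 2 of 12 ended the ribosomal call (0.0883 without the first intact PRL and 0.0795 without the second intact untreated library). Other settings gave larger G2-M differences that the preset test still called: 0.473 with a term for runs of title numbers (adjusted p = 2.07e-08), 0.553 without both second intact libraries (3.81e-12) and 0.981 without the second intact PRL library. These preset p-values take a correlation of 0.01 between genes. It was estimated at 0.682 for the G2-M list and 0.275 for the ribosomal list in the averaged PRL effect. Preset p-values can therefore be small without a difference that repeats across libraries. Over all leave-outs the G2-M median ran from -0.152 to 0.981 and the ribosomal one from 0.0795 to 0.307. A difference in how the 2 receptor pairs let PRL act on growth remains an open biological explanation and was not tested beyond these values.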

How the results depend on the processing

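Genes named by the rule and genes called in the main test were followed under the alternatives, and none reversed. Of their 7039 values, 6654 kept their side of the threshold, 128 lost and 257 gained a call, and 461 uncalled ones changed sign. Other genes named in the report were not followed in this way, among them HBEGF, TNS4 and CDH1. Of 1092 list values, 838 were the same, 248 lost their call and 6 reversed. Depth limits genes with few counts, such as PPIAP43, LTF and MUC17 (mean counts 7, 5.25 and 8.92). The main tests were not paired, because the labels give no shared replicate numbers. The term for runs of title numbers is a block found from the data, not a pairing the labels give, and rests on a hint, each library being closest in deviation to its own run. Where no reason is given below, the cause was not tested. The GC and length offset, the run term, leaving out both second intact libraries, and 2 list settings were chosen after seeing the data.

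Counts are given for PRL with intact and deleted I-tail and averaged (3, 3 and 21 as reported), then for the deletion in untreated and PRL-treated cells and averaged (1, 1 and 1). Library size alone gave 1 and 1, then 0 and 0; it shifted the median of all genes by -0.122 and -0.102 for PRL intact and averaged and by 0.101 for the deletion with PRL. Without a count filter there were 46, 33 and 124, then 6, 4 and 33. DESeq2 gave 22, 20 and 91, then 4, 2 and 10, and limma-voom 25, 21 and 116, then 5, 2 and 8. Compared groups only gave 1 and 11, then 0 and 0, with the libraries and the tested genes (16329 to 16698) changed at once. With 1 surrogate variable there were 52, 46 and 160, and 4 averaged deletion genes; with the run term 62, 57 and 198, and 11; with the GC and length offset 11, 15 and 62, and 3. A log2 fold change of at least 1 left 13 averaged PRL genes by construction. Without both second intact libraries there were 9 PRL genes with the deleted I-tail and 0 deletion genes in untreated cells. All 21 genes were shared by no filter, DESeq2, limma-voom, the surrogate variable and the run term, and 18 by the GC offset.

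Leave-outs of 1 library ranged from 1 to 4, 1 to 5 and 11 to 27 for PRL and from 0 to 1, 0 to 1 and 1 to 2 for the deletion; the interaction stayed at 0 in all (edgeR, 127 genes at unadjusted p under 0.05 as reported), and the response size ran from -0.192 to 0.0712. Counts of lists (10, 9, 11, 9, 3, 8 and 2 as reported) ranged from 6 to 12, 7 to 13, 7 to 15, 0 to 12, 2 to 10, 1 to 11 and 1 to 12. With an estimated correlation and with fry in 1 direction alike, 4 lists were called for averaged PRL and 0 for each other contrast. Without both second intact libraries 4 lists were called for PRL intact, 7 averaged and 5 for the deletion untreated. For the deletion with PRL, 5 were called with the run term, 5 with the GC offset and 6 with the surrogate variable, and for the interaction 4 with the run term and 4 with the surrogate variable.

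Over the leave-outs, medians of lists with a reversal ran from -0.0605 (without intact PRL library 2) to 0.442 for cholesterol synthesis with PRL intact and from -0.0448 (without intact PRL library 2) to 0.517 for G2-M with PRL averaged. With the deletion untreated they ran from -0.586 to 0.0568 (without intact untreated library 2) for G2-M, which was 0.0682 without both second intact libraries, and from -0.0168 (without deleted untreated library 3) to 0.621 for basal markers, which stood at 0.0598 without intact untreated library 1 (test direction reversed).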

Other observations

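The GC and length offset, the run term, the genes they add, the test of a general difference between cell lines, the values per locus and the splits balanced over runs were chosen only after the result was seen.

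When the axis across libraries was modelled, further PRL genes passed in the averaged effect. With 1 surrogate variable, TNS4, a focal adhesion gene, rose by 1.03 ± 0.07 (adjusted p = 3.9e-07), CITED4, a transcriptional coactivator, by 1.24 ± 0.12 (adjusted p = 7.63e-05), ID2 by 1.09 ± 0.11 (adjusted p = 3.26e-05) and LBH by 2.01 ± 0.25 (adjusted p = 8.04e-04), while BMP4, a growth factor of the TGF-beta family, fell (-1.10 ± 0.17, adjusted p = 0.00185) and the Notch target HES1 fell (-0.76 ± 0.16, adjusted p = 0.0488). Without it these stood at adjusted p = 0.178, 0.068, 0.221, 0.0592, 0.0761 and 0.229. In all 3 such settings (surrogate variable, run term, GC and length offset) 60 genes were called, 18 of them among the 21.

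With the run term, the averaged deletion effect called 11 genes. Among those that stood higher with the deletion were CDH1, which encodes E-cadherin (0.84 ± 0.12, adjusted p = 0.0152), the splicing regulator ESRP1 (0.93 ± 0.12, adjusted p = 0.00624), S100A14 (0.78 ± 0.10, adjusted p = 0.00408) and the basal keratin KRT14 (0.50 ± 0.08, adjusted p = 0.0271). These 4 were picked from the 11 after their values were seen, no list test was made of the 11, and without the run term each had adjusted p = 0.991.

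The rise in PRL calls when library structure is modelled was weighed first. A difference in GC content and length bias between libraries is a candidate explanation of the hidden spread: the offset for both raised the averaged count from 21 to 62, though less than the surrogate variable. Calls invented by the covariate stay open: 99.28% of the 139 genes gained with the surrogate variable had the same sign of PRL effect in both receptor pairs without it, against 65.75% of all genes, but they were selected for a large averaged effect, which favours equal signs. Deviations of libraries in the same run of title numbers correlated with a median of 0.253 against -0.204 across runs, and all 12 libraries were closest to 1 of their own run. The labels give no batch, so a shared day of culture or preparation may lie behind the runs and remains open.

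The level of EWSAT1, GIMAP6 and MB with the deletion was weighed second. Against a change of at least 0.5 shared by the neighbours, the 40 measured genes that start within 500 kb had a median shift of -0.173 ± 0.0908 in the direction of the gene, with -0.02 ± 0.18 over 11 near EWSAT1, -0.25 ± 0.13 over 22 near GIMAP6 and 0.16 ± 0.14 over 7 near MB, while a change limited to 1 neighbour, such as GIMAP2 (1.33 ± 0.75, adjusted p = 0.991), stays open. Against a GC and length trend as the whole cause, at least 0.964 of each log2 fold change was kept with the offset. A difference between 2 separately grown cell lines stays open: 1 gene was called for the averaged deletion effect (11 with the run term) and 21 for the averaged PRL effect, but the PRL count sets no bound for such a difference. It may account for these 3 genes, as may the receptor's I-tail, since the labels name no independent lines per receptor.

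Other splits of the same libraries were counted against each number of called genes. They exchange libraries freely across the runs of title numbers, so their counts mix run structure with chance, and chance can be excluded only as far as such splits allow. For the averaged PRL effect 4 of 100 splits called at least 21 genes (highest other 5091), and for the averaged deletion effect 4 of 100 called at least 1 gene (highest other 5145). The real splits have 2 libraries of each run on each side, and none of the 25 and 19 other drawn splits of that kind called a gene. For the interaction edgeR called 0 genes (127 at unadjusted p under 0.05, and 0 by DESeq2 and limma-voom), so 100 of 100 splits call as many by definition and decide nothing (highest other 2050). The 5091 and 5145 splits put all 4 libraries of the first run on 1 side, as did a PRL split with 2733 calls. Other splits of that kind called 0 genes, among them a PRL split with the same numbers per run as the 5091 split. A PRL split with at most 3 libraries of any run on 1 side called 465 genes. The place of the first run thus does not by itself decide the calls. With the run as a term, 198 and 11 genes were called. The 6 libraries of a single comparison make 10 splits, too few for a share under 0.05: for PRL with the intact I-tail 2 splits called at least 3 genes (highest other 1842), with the deleted I-tail 1 split (3 and 0), and for the deletion in untreated and PRL-treated cells 1 split each (1 and 0).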
